A study of Mus musculus with 8 samples.

How the data were processed

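The 4 libraries of the nude mouse experiment hold cells from bone scaffolds implanted under the skin of the flank and taken on day 14: mineralized or demineralized, without tumor cells or seeded with 400000 MDA-MB-231 cells. The scaffolds were 6 mm wide and 1 mm thick. According to the protocol, part of the scaffolds collected per condition was digested with dispase and collagenase, passed through a 40 µm strainer, cleared of red cells and loaded for 5000 cells per sample on a 10x Chromium. The authors deposited UMI counts per gene and barcode for each library, as filtered matrices from Cell Ranger 6.1.1 against a combined reference of 33538 human (GRCh38) and 31053 mouse (mm10) genes. The annotation release and the settings of the barcode filter are not given in the sources used here. For the immunocompetent experiment the authors deposited a table with the name of the sample tag called for each barcode (other: names, not values), together with the probability of that call as a fraction between 0 and 1. Its 6 columns with the probability of each tag were not used here. The expression counts of that pool, 2 expression libraries of mixed conditions, were not used either. Gene symbols and gene identifiers are those of the deposited feature tables.

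The libraries in the order tumor-free mineralized, tumor-free demineralized, tumor mineralized and tumor demineralized held 18849 barcodes together. A barcode was called human or mouse when at least 90% of its UMIs came from genes of that species. Cells needed at least 200 genes of their species and at most 20% mitochondrial UMIs, which removed 352, 359, 33 and 32 barcodes for genes and 235, 200, 145 and 185 for mitochondrial UMIs. Within each library and species, the barcodes with the highest doublet scores (Scrublet in scanpy 1.11.5) were removed at the expected rate of 0.8% per 1000 barcodes, 245, 208, 99 and 101 mouse and 4 and 16 human ones. This left 5003, 4614, 3395 and 3591 cells. Medians were 2499, 2682, 2839 and 2870 mouse genes per mouse cell and 3792 and 3970 human genes per human cell.

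Mouse cells of all libraries were clustered together with no batch correction: counts per 10000 on a log scale, 2000 variable genes, 30 principal components, 15 neighbors and Leiden clustering at resolution 1.0, with seed 0, which gave 25 clusters. Clusters were named from 16 marker lists fixed before the data were examined, as were the filters, the gene lists, the comparisons and the rule for named genes. How a marker's fold was taken (over the equal-weight mean of the other clusters) was chosen after the clusters were seen. The 111 cells of 1 cluster without a name were left out of the classes. UMIs were summed over the cells of each class in each library and scaled to CPM of the human or mouse total of that class. Ratios are log2 of (CPM + 10) over (CPM + 10), which draws the ratios of genes with low CPM towards 0. Intervals of the underlying count ratios are exact conditional binomial intervals with no pseudocount, so they lie on another scale than the log2 ratios and need not contain them. Intervals of shares are Clopper-Pearson and those of single CPM values are Poisson, each at 95%.

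A gene counted as measured in a ratio with at least 20 UMIs over both sums together and at least 10 CPM in either. Of 41 gene lists fixed for human or mouse cells, those with at least 5 measured members were read, in tumor cells and in the host classes with at least 50 cells in each library. The lists for neutrophils and for cytotoxic lymphocytes were not read, since these classes had fewer cells. A list is given by the median of its measured members and by the percentile of that median among 10000 random lists of the same size, drawn from measured genes in 20 bins of like expression. In tumor cells the named genes are the 12 highest and the 12 lowest log2 ratios whose interval excludes a ratio of 1. In the 3 host classes with the most cells they are 8 per direction, by the smaller of the log2 ratios of the 2 pairs, where both have the same sign and intervals that exclude 1. Of the genes this rule names in fibroblasts, 1 is not reported here. Mitochondrial, ribosomal and hemoglobin genes, XIST and unnamed gene models were left out, as were genes below 10% of the CPM of another class in every library, whose counts can come from free RNA. List members are named by their abundance or by a log2 ratio above 1 or below -1, and a few were picked after their values were seen. Mineralized was set over demineralized within the tumor-free and within the tumor libraries, and tumor over tumor-free within each scaffold type, so the pairs of each comparison share no library. Both comparisons use the same 4 libraries, so they are not independent of each other. With 1 library per condition no test was made, and cells of a library were not treated as replicates.

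Precision was tested on simulated data: Poisson counts drawn at the depth of these libraries from the mean expression of a pair, with known genes raised or lowered. In tumor cells, with 7974 genes, intervals excluded 1 in the right direction for 73.8% of genes set 1.5-fold apart, 98.5% of genes set 2-fold apart and 100% of genes set 4-fold apart, and 95.6% of intervals held the true ratio. In macrophages of the tumor pair, with 7424 genes, 97.0% of genes set 1.5-fold apart were recovered. In endothelial cells of the tumor-free pair, with 7784 genes, 40.0% were recovered at 1.5-fold and 76.6% at 2-fold. A list of 20 genes raised 1.5-fold lay at percentile 100 in each comparison, and of 40 unraised lists 2, 0 and 1 lay outside the percentiles 2.5 and 97.5. The counts were drawn independently for each gene, with no spread between cells and no correlation between genes. The simulation thus shows counting error only, and intervals and list percentiles of the real data can be less reliable.

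The alternatives tried were a species call at 75%, at least 500 genes per cell, at most 10% mitochondrial UMIs, no doublet removal and Leiden resolutions of 0.5 and 2.0. For expression they also were median-of-ratios scaling, a mean over cells of each cell's CPM, a pseudocount of 1 CPM, no filter on low counts beyond 1 UMI, and thinning each human cell to 2000 or each mouse cell to 1000 UMIs. For the tags, calls were counted only at a probability of 0.99 or more. After seeing the data a pair of settings was added: classes without clusters that 1 library fills to 90% or more (cluster 5), and classes without the clusters (1, 15 and 23) that a marker of another class leads when the fold is taken over the pooled rest. The work was done in Python 3.11.15 with scanpy 1.11.5, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0, igraph 0.11.9 and matplotlib 3.10.9.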

Results

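Single-cell RNA sequencing was done on cells recovered from bone scaffolds on day 14 after they were placed under the flank skin of athymic nude mice, which lack a thymus. The scaffolds were discs of decellularized bovine bone that either kept their mineral or had been demineralized with EDTA. They were implanted empty or seeded with MDA-MB-231, a human breast cancer cell line. The 4 conditions (tumor-free mineralized, tumor-free demineralized, tumor mineralized, tumor demineralized) were 1 library each, so no test between conditions was made and no p-value is given. In that order the libraries held 5835, 5381, 3685 and 3948 barcodes, 47600670, 45191420, 42649858 and 47140080 UMIs, and medians of 6814, 7771, 9396 and 10595 UMIs per barcode. After filtering, 5003, 4614, 3271 and 3095 mouse cells remained, with medians of 7541, 8559, 9515 and 9893 mouse UMIs. Intervals given below are exact 95% intervals of the counts, which cover counting error only and not differences between animals, scaffolds or preparations.

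The comparison of the tumor libraries asked how many tumor cells each scaffold held and what they expressed. Human cells were 124 of 3395 cells on the mineralized scaffold, 3.65% (3.05 to 4.34%), and 496 of 3591 on the demineralized scaffold, 13.8% (12.7 to 15.0%). The share was 3.78-fold higher without mineral (3.10 to 4.64). No human cell passed the filters in the tumor-free libraries, 0 of 5003 and 0 of 4614, which allows shares of up to 0.0737% and 0.0799%. Scaffolds had been picked for sequencing by their bioluminescence, and the share also depends on how many host cells came off each scaffold. The human cells had similar depth, with medians of 16470 and 16778 human UMIs.

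Tumor cells on the mineralized scaffold had more RNA of hypoxia response genes than those on the demineralized scaffold. Of the 18 listed genes, all measured, 17 were higher, with a median log2 ratio of 0.39 (percentile 100 among random lists of like expression, given here and below only as a description of these libraries). The most abundant were NDRG1, a gene induced by low oxygen (log2 0.85, 398 against 217 CPM, found in 108 of 124 and 382 of 496 cells), DDIT4 (0.53), ADM, which encodes the vasodilator peptide adrenomedullin (0.52), and BNIP3 (0.41). The glucose transporter gene SLC2A3 (0.79) and the carbonic anhydrase gene CA12 (0.84) were higher too, while the 15 glycolysis genes had a median of -0.03 (percentile 35.5). The immediate early and heat shock genes that respond to tissue dissociation moved with the hypoxia genes. Of 15 measured, 12 were higher, with a median of 0.31 (percentile 100), among them EGR1 (0.79), DUSP1 (0.56), FOS (0.46) and JUNB (0.29), while the abundant HSPA8 was at -0.10.

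Cell cycle genes of the tumor cells differed by phase. Of 31 measured S phase genes, 26 were lower on the mineralized scaffold, with a median of -0.20 (percentile 0.0), including TYMS (-0.51) and PCNA (-0.35). Of 44 measured G2 and M phase genes, 39 were higher, with a median of 0.22 (percentile 100), including CENPF (0.67), but the abundant UBE2C (-0.17) and TUBB4B (-0.15) were lower. With every human cell thinned to 2000 UMIs the medians were -0.11 (percentile 19.7) and 0.09 (percentile 92.2). Both lie inside the range that holds 95% of random lists, so neither difference stands out at that depth. The stem cell list had a median of 0.19 (percentile 99.3) over 6 measured genes, with MYC at 0.35 and KLF4 at 0.27, and its median was 0.00 when no gene was left out for low counts.

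The other tumor cell lists had medians inside the range that holds 95% of random lists. The median was 0.13 for NF-kB inflammatory genes (percentile 96.9, CXCL8 0.48), 0.12 for type I interferon response genes (97.4), 0.07 for extracellular matrix genes (92.2) and 0.07 for epithelial genes (92.4). It was 0.01 for MHC class I presentation (72.4), 0.01 for unfolded protein and amino acid stress (63.9) and 0.00 for cholesterol synthesis (43.3). It was -0.04 for bone metastasis genes (26.7), with BMP4 at 0.32 and DKK1 at -0.04, -0.06 for integrins and focal adhesion (18.6) and -0.08 for oxidative phosphorylation (9.57). It was -0.08 for YAP and TAZ targets (7.22), -0.11 for matrix proteases and inhibitors (5.39) and -0.13 for mesenchymal genes (3.50). With at most 10% mitochondrial UMIs some left that range: mesenchymal genes at -0.30, epithelial genes at -0.19 and matrix proteases at -0.16. Others that did were mesenchymal genes at -0.15 with no doublet removal, matrix proteases at -0.18 and glycolysis genes at 0.11 as a mean over cells, bone metastasis genes at 0.25 with thinned cells and NF-kB genes at 0.08 with no filter on low counts.

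Among single genes of the tumor cells, the 12 highest on the mineralized scaffold included NR2F1, a nuclear receptor gene linked to tumor cell dormancy (0.91, 127 against 63.1 CPM), and COLGALT2, which encodes a collagen galactosyltransferase (0.92). The interferon-induced IFIT1 (1.24), IFIT2 (1.13), HERC5 (1.06) and IFIT3 (0.85) came mostly from 1 of the 124 cells, which held 246 of 262, 132 of 146, 100 of 111 and 133 of 155 of their UMIs. Without cells over 10% mitochondrial UMIs these genes were lower on the mineralized scaffold, with IFIT1 at -1.55, HERC5 at -0.66 and IFIT3 at -1.51. The removed cells held 98.5% of IFIT1, 100% of IFIT2, 94.6% of HERC5 and 94.2% of IFIT3 UMIs there, which left few to compare. On the demineralized scaffold 3 cells held 69.2, 62.05, 48.5 and 51.3% of them, so no difference is read in either direction. TENT5A (0.91) had 62 of 121 UMIs in 1 cell and was at -0.14 without cells over 10% mitochondrial UMIs, and GAS2L3 (0.82) had 56.1% of its UMIs in 3 cells. The 12 lowest genes included the widely found keratin genes KRT7 (-0.66, 466 against 744 CPM, in 112 of 124 and 468 of 496 cells) and KRT81 (-0.66, 355 against 566 CPM). They also included the myosin light chain gene MYL9 (-0.72), the activin-binding FSTL3 (-0.71) and THBS1 (-0.65). HMOX1, which encodes heme oxygenase (-1.30), had 117 of 361 UMIs of the demineralized library in 1 cell, and was at 2.68 against 20.3 CPM without the 3 highest cells of each library. The others drew many of their UMIs from few cells or had few UMIs. DHRS2 (-1.11) had 115 of 115 there in 1 cell, and KRT17 (-0.73) had 99 of 162 and turned to 0.29 with cells thinned to 2000 UMIs. KRT14 (-0.69) had 73.1% of its UMIs in 3 cells and TAGLN (-0.87) had 50.3%, DIRAS3 (-0.71) had 30 of 117 in 1 cell, and SFTA1P (-0.68) had 7 and 106 UMIs.

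The host cells were sorted into classes to ask which cell types each scaffold held. Class names come from marker genes and stand for fibroblast-like, macrophage-like cells and so on. Fibroblasts were the largest class, at 46.8, 57.6, 46.7 and 46.0% of mouse cells in the tumor-free mineralized, tumor-free demineralized, tumor mineralized and tumor demineralized libraries, followed by macrophages and monocytes at 34.8, 31.4, 31.9 and 31.0%. Neutrophils were more frequent on mineralized scaffolds. They were 174 of 5003 cells (3.48%) against 4 of 4614 (0.0867%) without tumor, 40.1-fold (15.4 to 149), and 90 of 3271 (2.75%) against 28 of 3095 (0.905%) with tumor, 3.04-fold (1.97 to 4.83). Set over tumor-free, their share with tumor was 0.791-fold (0.606 to 1.03) on mineralized and 10.4-fold (3.65 to 40.9) on demineralized scaffolds. Pericytes and smooth muscle cells were 10.8% of mouse cells (9.72 to 11.9%) in the tumor demineralized library, 2.28-fold the share without tumor (1.92 to 2.72), against 4.78, 4.72 and 5.56% in the other libraries. Endothelial cells were 3.91% there, 2.15-fold the share without tumor (1.61 to 2.87), and 2.22, 1.82 and 2.66% in the other libraries.

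The shares of some host classes depended on the settings. The dendritic cell class is 1 cluster with 4 markers of its class among its leading genes. Retnla and Ccr2, markers of macrophages and monocytes, are among them too, so its name is less certain. Dendritic cells were 5.14% and 6.45% on mineralized and 2.25% and 2.62% on demineralized scaffolds, but at a Leiden resolution of 2.0 the tumor-free ratio of mineralized over demineralized was 0.521 in place of 2.28 and the tumor ratio 1.60 in place of 2.47. The tumor-free ratio was also 0.978 with a species call at 75% and 1.01 with at least 500 genes per cell, so no tumor-free difference is read from it. Cluster 5, which drew 94.2% of its cells from the tumor-free demineralized library, held 39.2% of the fibroblasts there. Cluster 1, which joins the macrophages under the naming used and not under a second scoring tried after seeing the data, was 19.2% of mouse cells in the tumor-free demineralized library and 5.60, 5.53 and 3.20% in the tumor-free mineralized, tumor mineralized and tumor demineralized ones. Without it the macrophage share ratio was 2.39 in place of 1.11 for mineralized over demineralized without tumor, and 2.27 in place of 0.988 for tumor over tumor-free on demineralized scaffolds. Cluster 1 drew 61.2% of its cells from the tumor-free demineralized library, so these shifts follow from leaving it out. No neutrophil cluster was found when cells needed at least 500 genes, since neutrophils had medians of 567 to 842 UMIs per cell.

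**Figure D1:**
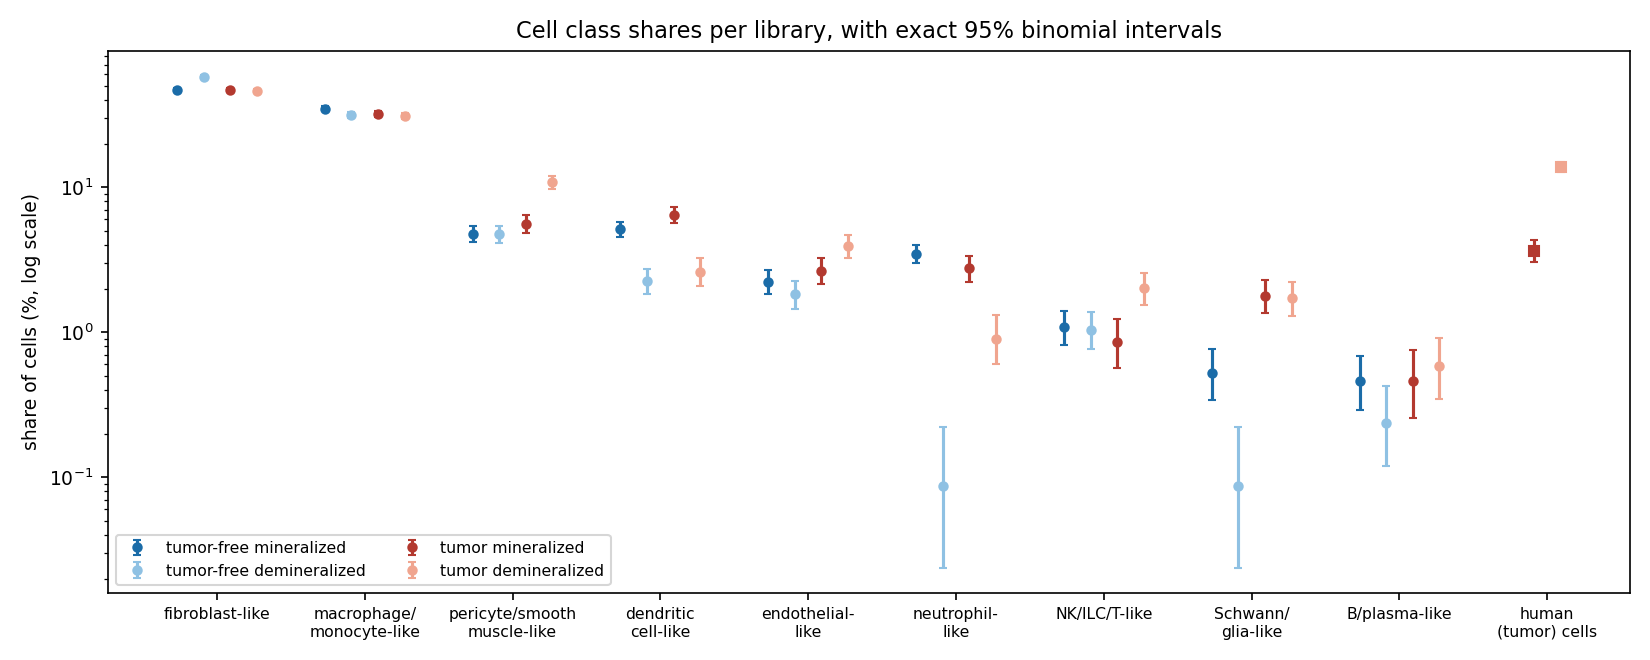
Share of mouse cells in each named class and of human cells among all cells of the tumor libraries (log axis, percent), with points for single libraries and bars for exact 95% binomial intervals, which cover counting error only. Neutrophils lie lowest in the tumor-free demineralized library (0.0867%) and human cells are higher on the demineralized (13.8%) than on the mineralized tumor scaffold (3.65%).

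Host expression was then compared between mineralized and demineralized scaffolds, once without and once with tumor, in pairs that share no library. Values below are log2 ratios for the tumor-free pair and then the tumor pair. Fibroblasts on mineralized scaffolds had more RNA of the acute phase genes Saa3 (5.06 and 2.54, 2544 against 66.7 CPM and 2287 against 386 CPM) and Hp, which encodes haptoglobin (3.00 and 1.85). They had more of Serpinb2, a plasminogen activator inhibitor gene (2.73 and 2.88), Il1rl1, the IL-33 receptor gene (1.75 and 1.67), Ereg, an EGF family ligand gene (1.56 and 2.27), Steap4 (1.69 and 1.66), Dhx34 (2.15 and 1.94) and Barx2 (1.72 and 1.67). Saa3 leads cluster 12, with 18.5% of fibroblasts on mineralized and 3.20% on demineralized scaffolds without tumor, and 21.7% and 13.5% with tumor. Serpinb2, Il1rl1 and Dhx34 are among the leading genes of cluster 15, with 14.9% and 3.99% without and 19.3% and 6.32% with tumor. How much of these ratios goes with the mix of clusters was not tested. Fibroblasts on demineralized scaffolds had more RNA of the matrix genes Col11a1 (-2.86 and -2.79), Fmod (-2.55 and -2.66), Col8a1 (-2.82 and -2.19) and Thbs1 (-2.86 and -1.89). They also had more of Igfbp2 (-4.05 and -2.77), Cpxm2 (-3.56 and -2.44), the complement regulator Cd59a (-2.03 and -1.89) and the contractile gene Tagln (-2.16 and -2.96), which without tumor lay under 10% of its CPM in pericytes. Over 7893 genes measured in both pairs the log2 ratios had a Pearson correlation of 0.640 across genes, which are not independent replicates, and 89 of the 92 genes at least 2-fold apart in both pairs had the same direction.

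Among the fibroblast lists, contractile genes were lower on mineralized scaffolds, 8 of 9 without tumor (median -0.53) and 11 of 12 with tumor (-0.90), with Tpm1 at -0.59 and -0.70 and Myl9 at -1.51 and -2.37. G2 and M phase genes were higher, 27 of 27 (0.71) and 23 of 28 (0.12), with Top2a at 1.10 and 0.13, and S phase genes likewise, 19 of 20 (0.41) and 17 of 20 (0.16). In the tumor pair, however, the G2 and M phase median was -0.02 as a mean over cells and the S phase median -0.06 with cells thinned to 1000 UMIs. Osteogenic genes, of which 6 of 18 were measured, had medians of -0.37 and -0.25, with Csf1 at -0.78 and -0.43 and Spp1 apart at 2.71 and -0.94, and were at -0.0018 and -0.019 with no filter on low counts. The extracellular matrix list was mixed (0.12 and -0.12, the latter 0.01 with thinned cells), with Col12a1 at -2.29 and -1.44 and the crosslinking enzyme gene Loxl2 at 1.12 and 1.19. Matrix proteases and inhibitors were at -0.46 and 0.05, with Timp1 at 1.62 and 0.92 and Timp3 at -1.23 and -1.38. Several lists had opposite signs in the pairs: inflammatory genes (-0.23 and 0.64, Cxcl1 -0.39 and 0.98), hypoxia genes (-0.21 and 0.33), glycolysis genes (-0.04 and 0.34) and type I interferon genes (0.32 and -0.76). The dissociation stress list was at -0.07 and 0.16. Without cluster 5, which held 39.2% of the fibroblasts of the tumor-free demineralized library and is led by Igfbp2, Cpxm2, Fmod, Col11a1 and Col8a1, the tumor-free medians were -0.01 for contractile, 0.30 for inflammatory and 0.09 for hypoxia genes, so the last 2 had the sign of the tumor pair. Tagln was then at -0.57, while Fmod was at -2.07, Col11a1 at -2.18 and Cpxm2 at -2.76.

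**Figure D2:**
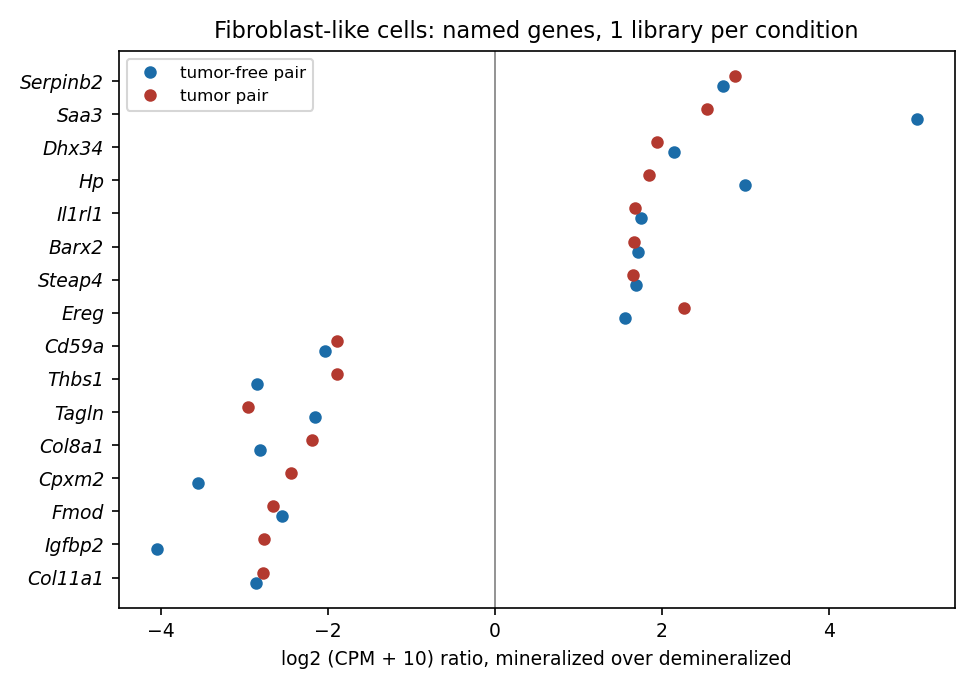
Log2 ratio of (CPM + 10), mineralized over demineralized, of the 16 genes named for fibroblasts, blue for the tumor-free pair and red for the tumor pair, with no error drawn because each condition is 1 library. The values run from Saa3 (5.06 and 2.54) to Igfbp2 (-4.05 and -2.77). Genes were named only where both pairs had the same sign, so that both lie on the same side of 0 follows from the choice.

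Macrophages and monocytes on mineralized scaffolds had more RNA of Fn1, the fibronectin gene (2.19 and 2.04, 1325 against 283 CPM and 1047 against 246 CPM), the neutrophil-attracting chemokine gene Cxcl3 (2.00 and 2.06), Lyz1 (1.49 and 1.29), the coagulation factor gene F7 (1.59 and 1.16), Mmp19 (1.15 and 1.25) and Bhlhe40 (1.01 and 1.34). On demineralized scaffolds they had more of the chemokine genes Ccl12 (-1.87 and -1.61) and Ccl7 (-1.81 and -0.77), the chemokine receptor gene Cx3cr1 (-1.06 and -1.30), Ch25h, which encodes cholesterol 25-hydroxylase (-1.62 and -1.49), Fcrls (-1.26 and -1.09), Gpr65 (-0.89 and -0.76), Id2 (-1.16 and -0.73) and Retreg1 (-0.77 and -0.72). The osteoclast-linked protease gene Ctsk (2.64 and 1.52) drew 65.2% of its UMIs in the tumor mineralized library from 3 cells and was at 0.78 in the tumor pair as a mean over cells. Cxcl3 drew 43.4% of its UMIs in the tumor mineralized library from 3 cells. Slpi, which is also on the marker list for neutrophils, was at 2.80 and 1.01. It had 6 UMIs in macrophages of the tumor-free demineralized library and drew 33.3% of its UMIs in the tumor mineralized library from 3 cells. Whether its RNA came from neutrophils was not tested. Over 7367 genes the pairs were nearly unrelated, with a Pearson correlation of 0.00991 across genes and the same sign for 45.3%.

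The largest macrophage cluster differed between libraries: cluster 2, led by Cd163, Lyve1 and Folr2, held 41.1% and 49.1% of them on mineralized scaffolds. Cluster 1, led by Il10, Ccl4 and Tnf, held 61.0% in the tumor-free demineralized library. Cluster 3, led by Cd72, Ccl12 and Ms4a4c, held 50.9% in the tumor demineralized library. Lipid and lysosome handling genes were higher on the mineralized scaffold without tumor, 17 of 18 with a median of 1.15, and less so with tumor, 13 of 18 with a median of 0.16 (0.07 at a Leiden resolution of 0.5), with Gpnmb at 3.58 and 0.22, Spp1 at 3.28 and -0.69 and Lpl at 1.35 and 0.96. Gpnmb and Spp1 are among the leading genes of cluster 0, which held 20.1% of macrophages on mineralized and 2.62% on demineralized scaffolds without tumor, and 8.13% and 6.67% with tumor. Within clusters, looked at after seeing the data, the lipid medians were smaller, at 0.37, 0.19 and 0.17 in clusters 1, 2 and 10 without tumor. They lay between -0.06 and 0.02 in 4 clusters with tumor. How much of the class value goes with the mix of clusters cannot be told from this. The clusters were drawn on the same genes, and cluster 0 is led in part by Gpnmb, Spp1, Fabp5 and Lgals3 of the list. Cluster 0 also had only 38 cells in the tumor-free demineralized library and was not compared without tumor. Osteoclast genes were at 0.95 and -0.00 and glycolysis genes at 0.35 and -0.00. Within clusters 1, 2 and 10 the osteoclast medians without tumor were 0.45, 0.13 and 0.13. With tumor the osteoclast median was 0.56 in cluster 0, with 9 of 11 genes higher, and -0.10, 0.07 and -0.08 in clusters 1, 2 and 3. Monocyte genes were higher in both pairs (0.46 and 0.38), with S100a4 at 1.04 and 0.81 and Lyz2 at 0.46 and 0.40, and G2 and M phase genes lower, 27 of 30 (-0.24) and 35 of 36 (-0.46). Inflammatory cytokine genes were at -1.51 without tumor, with 11 of 14 lower, and at -0.09 with tumor, with 7 of 14 lower, a difference that was not tested. Ccl4 was at -2.18 and -0.59, Cxcl2 at -1.63 and 0.28 and Tnf at -1.49 and 0.16. The dissociation stress list was at -0.31 and 0.53. The remaining lists had opposite signs: MHC class II presentation (-0.70 and 0.33, the latter -0.00 with thinned cells), alternative activation (-0.19 and 0.52, Retnla -1.11 and 1.19, Mgl2 -1.50 and 2.00), complement and resident macrophage genes (-0.24 and 0.47, Cd163 0.44 and 1.72), hypoxia (-0.23 and 0.13), type I interferon (0.14 and -0.67) and S phase (0.05 and -0.40). Without cluster 1, left out after seeing the data because a marker of another class led it in a second scoring, the tumor-free values were -0.39 for cytokine genes, 0.17 for monocyte genes, 0.00 for Gpr65, 0.15 for Id2, -0.54 for Ch25h and -0.92 for Ccl12. The cytokine shift follows from leaving out a cluster that genes of that list lead.

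Pericytes and smooth muscle cells on mineralized scaffolds had more RNA of the endothelin receptor gene Ednrb (1.69 and 2.37), the imprinted RNA H19 (1.60 and 2.64), Ifitm1 (1.59 and 1.73), Enpp2, which encodes autotaxin (1.22 and 1.63), Spns2 (1.09 and 1.78) and Parm1 (1.04 and 1.17). The class joins cluster 17, led by pericyte genes such as Rgs5, with cluster 19, led by Myh11. Cluster 19 held 19.7% of the class on mineralized and 11.01% on demineralized scaffolds without tumor and 23.6% and 4.79% with tumor. Within cluster 17, looked at after seeing the data, the named genes kept their signs, but Tesc, a leading gene of cluster 19, was at 0.77 with tumor against 2.25 in the whole class. On demineralized scaffolds they had more of the thrombin receptor gene F2r (-1.84 and -1.82), Basp1 (-1.99 and -0.87), the activin antagonist gene Fst (-0.86 and -0.88), Foxc2 (-0.79 and -0.98), Col8a1 (-0.78 and -1.33) and Odc1 (-0.82 and -0.77). Hp (3.16 and 1.72) rested on few cells, with 89 of 116 UMIs of the tumor-free mineralized library in 1 of 239 cells, Klk8 (-1.46 and -1.75) drew 78.3% of its UMIs in the tumor mineralized library from 3 cells, and Cfap43 (-0.87 and -0.80) turned to 0.23 in the tumor-free pair with cells thinned to 1000 UMIs. G2 and M phase genes were lower on mineralized scaffolds, 30 of 38 without tumor (-0.19) and 39 of 39 with tumor (-1.004), with Mki67 at 0.08 and -1.31 and Cdk1 at -0.23 and -1.23. Glycolysis genes were at -0.29 and -0.35, hypoxia genes at -0.30 and -0.17, S phase genes at 0.02 and -0.32, type I interferon genes at 0.46 and -0.64 and dissociation stress genes at -0.05 and 0.52. With cells thinned to 1000 UMIs the hypoxia median of the tumor-free pair was 0.10 and the S phase median of the tumor pair 0.15, and with no doublet removal tumor hypoxia was at 0.01. The Pearson correlation of the pairs was 0.104 across 8201 genes.

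Endothelial cells on mineralized scaffolds had lower angiogenic genes, 14 of 19 without tumor (-0.45) and 13 of 19 with tumor (-0.41). Among them were the growth factor gene Pgf (-3.11 and -1.84), the tip cell genes Apln (-1.92 and -1.76) and Esm1 (-1.87 and -1.35), and the basement membrane gene Col4a1 (-0.45 and -0.49), while the leukocyte adhesion gene Selp (1.41 and 1.54) and Ackr1 (0.94 and 1.18) were higher. Their hypoxia genes (-0.31 and -0.22) and glycolysis genes (-0.39 and -0.19) were lower and their G2 and M phase genes higher (0.35 and 0.46). Several of these shrank under alternatives. Tumor hypoxia was at -0.08 with at most 10% mitochondrial UMIs. Tumor glycolysis was at -0.06 as a mean over cells and -0.10 with cells thinned to 1000 UMIs. G2 and M phase was at 0.22 and 0.32 as a mean over cells, and tumor-free angiogenic genes at -0.21 with thinned cells. Interferon genes were at -0.07 and -1.17, S phase genes at 0.26 and -0.03 and dissociation stress genes at 0.11 and 0.04. Dendritic cells had medians of 0.43 and -0.02 for S phase, 0.28 and -0.28 for G2 and M phase, 0.15 and 0.06 for hypoxia, 0.10 and 0.22 for glycolysis, 0.51 and -0.52 for interferon and 0.00 and -0.07 for dissociation stress. The tumor-free G2 and M phase median was -0.37 with cells thinned to 1000 UMIs, and at a Leiden resolution of 2.0 tumor-free hypoxia was at -0.42 and tumor glycolysis at -0.09. The pairs had Pearson correlations of 0.118 for endothelial cells and 0.0551 for dendritic cells across genes.

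The comparison of tumor with tumor-free libraries, made on each scaffold, asked how host cells differ where tumor cells are present. Values are log2 ratios on the mineralized and then on the demineralized scaffold. Type I interferon response genes were higher with tumor in all 5 host classes on both scaffolds. The medians were 0.62 and 1.44 in macrophages, where 19 of 19 genes were higher in both pairs, 0.27 and 1.37 in fibroblasts (12 of 12 and 14 of 14), 1.08 and 1.69 in pericytes (13 of 13 and 15 of 15), 1.24 and 2.54 in endothelial cells (15 of 15 and 16 of 16) and 0.30 and 1.26 in dendritic cells (12 of 16 and 10 of 12). Within clusters the macrophage medians were lower than in the whole class, at 0.01, 0.16, 0.08 and -0.19 in 4 clusters on the mineralized and 0.79 and 0.74 in clusters 1 and 2 on the demineralized scaffold. The fibroblast medians on the mineralized scaffold were mixed, at 0.27, 0.27, -0.36, -0.11, 0.13 and 0.06 in clusters 11, 12, 13, 14, 15 and 18. Cluster 3, led in part by interferon-induced genes such as Ifit2 and Ifi44, held 1.24% of macrophages without and 50.9% with tumor on demineralized scaffolds, and 10.6% with tumor on the mineralized one. In macrophages Isg15 was at 1.14 and 1.48, Ifit3 at 1.17 and 2.32 and Ifi27l2a at 0.74 and 1.46, and in endothelial cells Irf7, a transcription factor gene of the response, was at 2.35 and 4.32. The median was higher on the demineralized than on the mineralized scaffold in each of the 5 classes, a difference that was not tested. Over all classes the median within single clusters was above 0.26 in 38.5% of 13 clusters on mineralized and in 100% of 10 clusters on demineralized scaffolds. Endothelial and dendritic cells were 1 cluster each, so their values in these counts are those of the class.

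**Figure D3:**
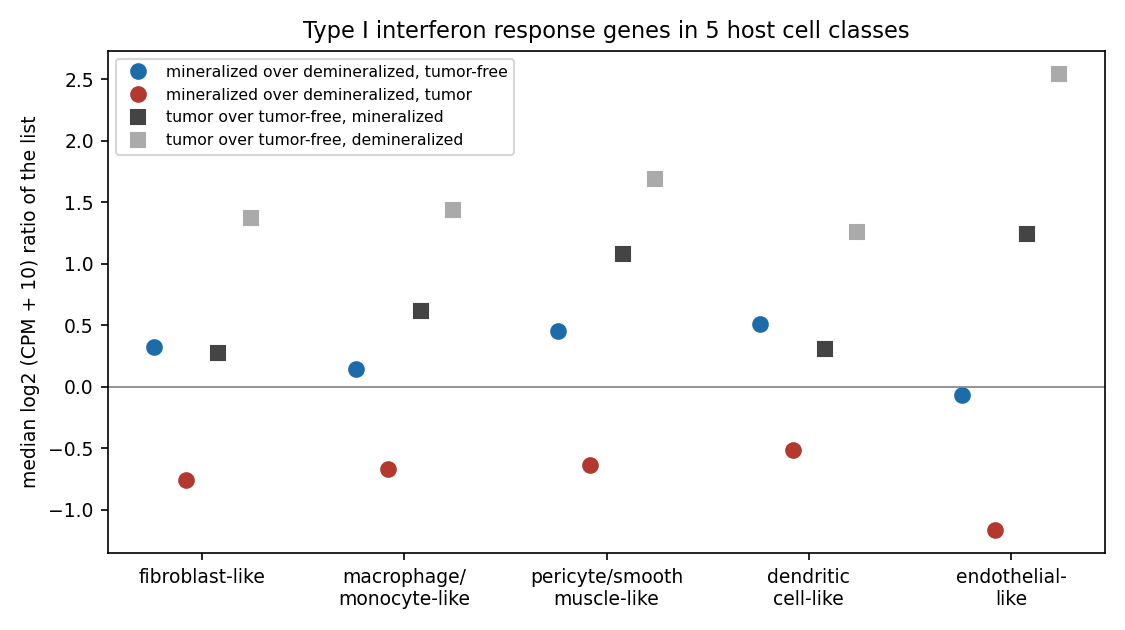
Median log2 ratio of (CPM + 10) of the type I interferon response list in 5 host classes, as circles for mineralized over demineralized (without and with tumor) and squares for tumor over tumor-free (on each scaffold), with no error drawn because each condition is 1 library. All 10 squares lie above 0, from 0.27 to 2.54.

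Fibroblasts of the tumor libraries had more RNA of the contractile genes Tagln (1.64 and 2.44) and Acta2 (1.18 and 3.30, 203 against 84.4 CPM and 1162 against 109 CPM), Cdkn2a, a cell cycle inhibitor gene (0.91 and 0.88), Dmkn (1.04 and 2.92), Akr1c18 (0.96 and 2.82) and Serpinb2 (0.90 and 0.75). The interferon-induced chemokine gene Cxcl9 (1.38 and 2.54) drew 63.9% of its UMIs in the tumor mineralized library from 3 cells. On the mineralized scaffold Tagln and Acta2 of fibroblasts lay under 10% of their CPM in pericytes with and without tumor. Tagln had 1013 UMIs in 230 of 2342 fibroblasts there without tumor and 3427 in 189 of 1528 with tumor. Acta2 had 2526 UMIs in 599 and 5519 in 557 of these cells. These counts argue against free RNA spread over all cells as their main source. With tumor 3 cells held 22.6% of the Tagln and 18.2% of the Acta2 UMIs, so the ratios on that scaffold rest on part of the fibroblasts. Lower with tumor were Ctla2a (-3.02 and -3.44), the lipase gene Lpl (-1.86 and -1.95), Scg2 (-2.79 and -4.74), Egfl6 (-2.35 and -2.58) and the tendon gene Tnmd (-2.18 and -2.33). Scg2, Egfl6 and Tnmd lead cluster 4, which held 9.82% and 20.4% of fibroblasts without tumor and 0.0655% and 1.33% with tumor. With a pseudocount of 1 in place of 10 CPM, Scg2 was at -5.55 and -6.03, since the pseudocount weighs on log2 ratios at low CPM. The developmental position genes Hoxc10 (-1.85 and -3.02, 6.67 against 50.04 CPM and 2.39 against 90.8 CPM), Hoxc11 (-1.79 and -2.16) and Hoxa10 (-1.47 and -2.25) were lower too. These posterior genes mark where on the body fibroblasts come from, and where on the flank each scaffold lay is not given in the sources used here.

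Contractile genes as a list were higher in fibroblasts with tumor, 8 of 9 (0.24) and 10 of 12 (0.93), with Myl9 at 0.09 and 0.94. The demineralized tumor library had 31.8% of its fibroblasts in cluster 16, led by C1qtnf3, Col12a1 and Kif26b, against at most 4.65% elsewhere. Other lists differed by scaffold. On the mineralized scaffold hypoxia (0.26), glycolysis (0.30) and protease genes (0.12) were higher, and on the demineralized scaffold they were at -0.21, -0.10 and -0.34. Inflammatory genes were at 0.07 and -0.61, with Il6 at 0.35 and -1.07 and Saa3 at -0.15 and 2.37. G2 and M phase genes were at 0.02 and 0.63, S phase genes at -0.06 and 0.14, extracellular matrix genes at -0.02 and 0.05, osteogenic genes at -0.05 and -0.13 and dissociation stress genes at -0.12 and -0.30. The Pearson correlation of the pairs was 0.422 across 7729 genes. Without cluster 5 the medians on the demineralized scaffold were 1.51 for contractile, -0.06 for inflammatory, -0.02 for hypoxia and 0.28 for osteogenic genes, and Acta2 was at 4.31.

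**Figure D4:**
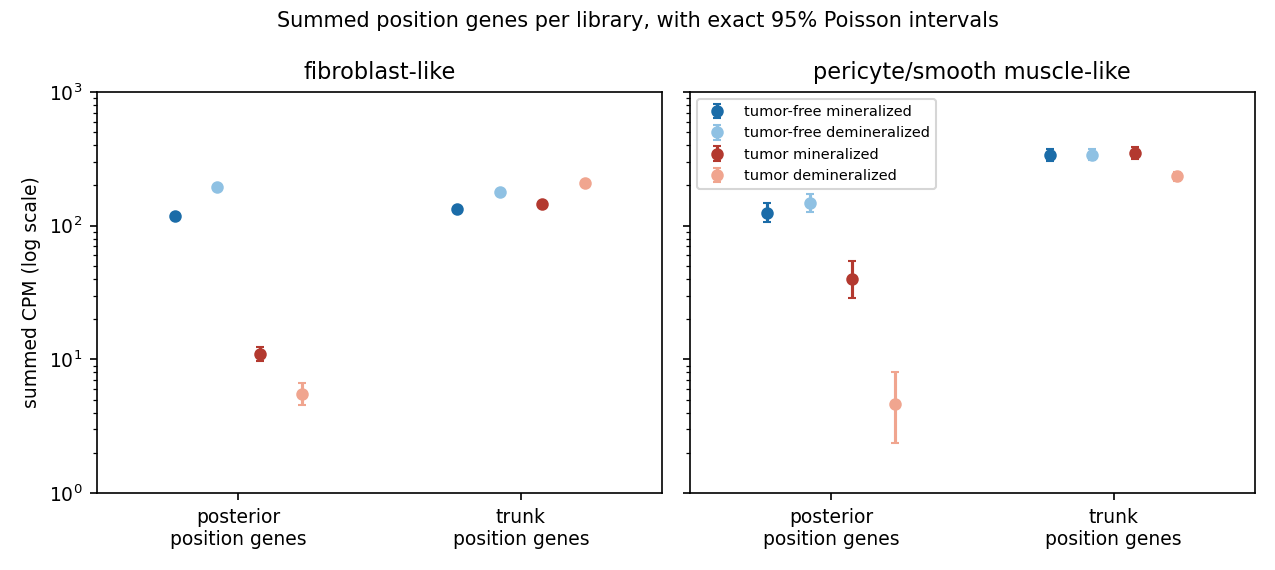
Summed CPM (log axis) of posterior position genes (Hox groups 10 to 13, Pitx1, Tbx4) and of trunk position genes (Hox groups 4 to 8) in fibroblasts and in pericytes of the 4 libraries, with exact 95% Poisson intervals. In fibroblasts the posterior sum is 119 and 195 CPM without tumor against 11.02 and 5.53 CPM with tumor, and the trunk sum lies between 133 and 210 CPM.

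Macrophages and monocytes of the tumor libraries had more RNA of Arg1, the arginase gene of wound and tumor macrophages (1.26 and 1.88), Lrg1 (1.46 and 1.21), Ms4a4c (1.23 and 2.64), Ifit2 (1.00 and 1.82) and the histone gene Hist1h1b (0.99 and 1.22). In the tumor mineralized library Arg1 was found in 49 of 1045 macrophages, with 42.8% of its UMIs in 3 cells, and Hist1h1b in 25, with 44.2%. The acute phase gene Saa3 was at 4.03 on the demineralized scaffold. Its 1.40 on the mineralized scaffold is not read as macrophage expression, since there it had 55.1 and 162 CPM in macrophages against 2544 and 2287 CPM in fibroblasts without and with tumor, a level open to free RNA. Lower with tumor were Rnase2a (-1.12 and -3.10), the chemokine gene Ccl24 (-0.64 and -1.40), Lpl (-1.09 and -0.69), Atp6v0d2, a proton pump subunit gene (-1.27 and -0.60), Pla2g2d (-1.07 and -1.01), Cd209b (-0.82 and -1.20), Qpct (-0.70 and -0.996) and Angptl7 (-0.65 and -0.80). G2 and M phase genes were higher, 22 of 29 (0.20) and 28 of 36 (0.31), but the mineralized median was 0.00 as a mean over cells, and the demineralized median was -0.20 without cluster 1. Lipid and lysosome genes were at -0.52 and 0.26, with Gpnmb at -2.90 and 0.47, and osteoclast genes at -0.30 and -0.00. On the mineralized scaffold the share of cluster 0 was lower with tumor, and the lipid medians within clusters 0, 1, 2 and 10 were -0.37, -0.15, 0.01 and -0.02. Monocyte genes were at 0.00 and 0.24, MHC class II genes at 0.54 and -0.28 and complement genes at 0.25 and -0.44. Inflammatory cytokine genes were at 0.21 and -0.97, with Tnf at -0.10 and -1.75, and the dissociation stress list had the same signs, at 0.12 and -0.76. Without cluster 1, which is led in part by Ccl4, Tnf and Ccl3 of this list, the cytokine median on the demineralized scaffold was 0.47. That shift follows from leaving the cluster out. With thinned cells the cytokine median was -0.10 on the mineralized scaffold. Alternative activation genes were at -0.05 and -0.65, hypoxia genes at 0.00 and -0.24, glycolysis genes at 0.03 and 0.56 and S phase genes at 0.03 and 0.40. The Pearson correlation of the pairs was 0.137 across 7362 genes.

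Pericytes and smooth muscle cells of the tumor libraries had more RNA of the interferon-induced genes Ifi44 (1.86 and 2.87), Zbp1 (1.47 and 2.66), Usp18 (1.46 and 1.69), Irf7 (1.40 and 3.45) and Iigp1 (1.21 and 2.29), and of Ctgf (1.51 and 2.60), Gpx3 (1.43 and 1.89) and Ly6a (1.19 and 3.02, the former under 10% of the CPM of fibroblasts in both libraries). With cells thinned to 1000 UMIs Usp18 was at 0.23 and Zbp1 at 0.20 on the mineralized scaffold. Lower were Fst (-1.56 and -1.54), the smooth muscle gene Cnn1 (-1.14 and -1.34), the angiotensinogen gene Agt (-1.12 and -1.05), Fbn2 (-1.35 and -1.002, the latter likewise), Pparg (-0.99 and -1.32), Olfm2 (-1.09 and -1.13) and the position genes Hoxc10 (-1.40 and -3.10) and Hoxa9 (-1.05 and -2.59). G2 and M phase genes were at -0.57 and 0.07, S phase genes at -0.32 and 0.13 (the latter -0.13 with thinned cells), hypoxia genes at 0.09 and -0.02, glycolysis genes at 0.03 and 0.05 and dissociation stress genes at 0.28 and -0.11. In endothelial cells hypoxia genes were at -0.11 and -0.53, angiogenic genes at 0.01 and -0.19, glycolysis genes at -0.00 and -0.15, G2 and M phase genes at -0.13 and -0.11, S phase genes at -0.16 and 0.12 and stress genes at 0.02 and -0.12. In dendritic cells S phase genes were at -0.52 and 0.10, G2 and M phase genes at -0.22 and 0.18, hypoxia genes at 0.11 and 0.03, glycolysis genes at 0.08 and 0.01 and stress genes at 0.15 and 0.18. The pairs had Pearson correlations across genes of 0.107 in pericytes, 0.204 in endothelial cells and 0.202 in dendritic cells.

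In a second experiment, scaffolds with or without 4T1.2, a mouse mammary tumor line seeded at 50000 cells, were placed in immunocompetent BALB/c mice and the 4 conditions were pooled with sample tags. Of 15583 barcodes in the tag table, 10294 carried 1 tag: 2383 for tumor-free mineralized, 1807 for tumor-free demineralized, 2497 for tumor mineralized and 3607 for tumor demineralized scaffolds. These were 23.1% (22.3 to 24.0%), 17.5% (16.8 to 18.3%), 24.3% (23.4 to 25.1%) and 35.0% (34.1 to 36.0%) of the tagged barcodes. A further 4821 barcodes were unassigned, 248 blank and 220 multiplets. The shares follow how many cells of each condition were pooled and recovered, so they are not a readout of the tumor or the scaffold, and the expression counts of this pool are not analysed here.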

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

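Of the tests in this part, those of implant position, of a tumor effect on Hox genes, of fewer neutrophils on scaffolds without mineral, the control for neutrophil free RNA, those of cluster mix for the interferon genes and of the tumor as their source were chosen after the results were seen, and the others before.

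Posterior position genes (Hox groups 10 to 13, Pitx1 and Tbx4) were lower in fibroblasts of the tumor libraries, at 11.02 against 119 CPM on mineralized and 5.53 against 195 CPM on demineralized scaffolds. A different mix of fibroblast clusters is excluded as the whole explanation. Within clusters the median log2 ratio was -3.55 over 6 clusters on mineralized and -5.08 over 5 clusters on demineralized scaffolds. Clusters 4 and 5, with 20.4% and 39.2% of the fibroblasts of the tumor-free demineralized library, had too few cells with tumor to be compared. Trunk position genes of fibroblasts were not lower (log2 ratios of 0.12 and 0.22), which is what scaffolds implanted further forward on the body would give. In pericytes posterior genes were lower too, at 40.0 against 125 CPM and 4.62 against 149 CPM, but on demineralized scaffolds their trunk genes were also lower, 0.691-fold (0.609 to 0.785). In endothelial cells posterior genes were 3.36-fold lower (1.52 to 8.41) on mineralized and 2.115-fold lower (1.36 to 3.34) on demineralized scaffolds. The latter is far less than the 35.3-fold of fibroblasts and 32.2-fold of pericytes there. A lowering of the posterior genes of fibroblasts by tumor cells (log2 -3.43 and -5.14) could not be separated from position, because the implant site of each scaffold is not given in the sources used here, so both stay open.

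Neutrophils were scarce in the tumor-free demineralized library, 4 cells against 174. Neutrophils lost among barcodes would leave free RNA in the suspension, and S100a8 and S100a9 in fibroblasts were at 0.284 against 6.99 CPM, a ratio of 0.0406 (0.0183 to 0.0786). This loss stays open, because that RNA does not track neutrophils: the tumor mineralized library, with 2.75% neutrophils, also had a ratio of only 0.174 (0.117 to 0.252). Removal by the filters is excluded, with 2 such UMIs in 481 removed mouse barcodes, a ratio of 0.00755 (0.000910 to 0.0276). Fewer neutrophils on scaffolds without mineral remain possible: the tumor pair had the same direction, 3.04-fold (1.97 to 4.83), but with 1 library per condition this cannot be told from a loss of cells before or after the suspension was loaded.

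Interferon response genes were higher in host cells of the tumor libraries. Human RNA counted on mouse genes is excluded, since it accounts for 0.00118% of the added UMIs in macrophages. On demineralized scaffolds 100% of 10 clusters had a list median above 0.26. For fibroblasts (0.35 to 1.77) and pericytes (1.7) this excludes a different mix of clusters as the whole explanation. The same holds for macrophages, with 0.79 and 0.74 in clusters 1 and 2, both below the class median. Cluster 3, with 50.9% of the macrophages with tumor, had 18 cells without tumor and was not compared there. On mineralized scaffolds a mix is excluded as the whole explanation in pericytes (100% of 1 cluster, 1.14). Endothelial (1.24 on mineralized, 2.545 on demineralized) and dendritic cells (0.30 and 1.26) were 1 cluster each, so their values test no mix. On mineralized scaffolds a different mix stays open in fibroblasts (33.3% of 6 clusters) and in macrophages (0 of 4), where cluster 3 is itself led in part by interferon genes. An effect of the tumor cells (lowest of the 10 medians 0.27) could not be separated from other differences between the libraries.

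The results that follow went opposite ways in the pairs of a comparison, and none of these differences was tested. Both comparisons use the same 4 libraries, so for a gene the difference between the pairs has the same size in either comparison. Hypoxia genes in fibroblasts and stress and complement genes in macrophages appear under both comparisons and are not separate results there. In fibroblasts, mineralized over demineralized without and with tumor, hypoxia genes were at -0.21 and 0.33, interferon genes at 0.32 and -0.76 and inflammatory genes at -0.23 and 0.64. In fibroblasts, tumor over tumor-free on mineralized and demineralized scaffolds, hypoxia genes were at 0.26 and -0.21 and proteases and inhibitors at 0.12 and -0.34. In macrophages, mineralized over demineralized without and with tumor, dissociation stress genes were at -0.31 and 0.53, alternative activation genes at -0.19 and 0.52, MHC class II genes at -0.70 and 0.33 and complement genes at -0.24 and 0.47. In macrophages, tumor over tumor-free on mineralized and demineralized scaffolds, stress genes were at 0.12 and -0.76, cytokine genes at 0.21 and -0.97 and complement genes at 0.25 and -0.44. In pericytes, S phase genes were at -0.32 and 0.13 for tumor over tumor-free, and interferon genes at 0.46 and -0.64 for mineralized over demineralized. In dendritic cells, mineralized over demineralized, G2 and M phase genes were at 0.28 and -0.28 and interferon genes at 0.51 and -0.52. Some of these opposite signs were lost under an alternative. Without cluster 5 the tumor-free fibroblast medians were 0.30 for inflammatory and 0.089 for hypoxia genes, and without cluster 1 the macrophage cytokine median was 0.47 (tumor over tumor-free, demineralized). Cluster 1 is led in part by Ccl4, Tnf and Ccl3 of the cytokine list and lay mostly in the tumor-free demineralized library. The cytokine shift thus follows from leaving it out. With cells thinned to 1000 UMIs, fibroblast inflammatory genes were at 0.25 (tumor-free), macrophage cytokines at -0.10 (tumor over tumor-free, mineralized), macrophage MHC class II genes at -0.00 (tumor), pericyte S phase genes at -0.13 (tumor over tumor-free, demineralized) and dendritic cell G2 and M phase genes at -0.37 (tumor-free).

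Signals outside the main measurement were human UMIs in mouse cells, 0.0914% of their UMIs in the tumor mineralized and 0.204% in the tumor demineralized library against 0.0465% and 0.0487% without tumor. Barcodes mixed between species that pass the filters numbered 9 and 23 in the tumor libraries and 0 in both tumor-free libraries.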

How the results depend on the processing

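The settings without cluster 5 and without clusters 1, 15 and 23 were chosen after seeing the data. Of 2496 gene values under alternatives, 2052 stayed within their interval on the same side, 435 moved and 9 reversed, of 2352 list values 2155, 178 and 19, and of 280 share values 252, 23 and 5. The tumor cell share stayed 3.74 to 4.10-fold higher without mineral, and the hypoxia list of tumor cells stayed between 0.35 and 0.52. No paired analysis was possible by replicate number because the labels give no replicate numbers and no result comes from a test. The pairs of each comparison were read side by side, and no fit that joins them was made. Depth limits the small classes: at 1000 UMIs 13 of 174 neutrophils of the tumor-free mineralized library were deep enough, and at 500 genes no neutrophil class was found, so these settings give no neutrophil values. A pseudocount of 1 moved 93 named gene values and left 123, and median-of-ratios scaling moved 16 and left 200. By the percentile rule they moved 5 and 3 list values, none of which leads a comparison. The cause was not tested for the values below.

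At least 500 genes per cell gave a B and plasma cell share ratio of 0.872 (tumor over tumor-free, demineralized), a dendritic cell share ratio of 1.01 (mineralized over demineralized, tumor-free), and in the tumor pair 0.13 for macrophage lipid genes, -0.14 for pericyte hypoxia and -0.18 for endothelial hypoxia. The species call at 75% gave dendritic cell share ratios of 0.978 tumor-free and 1.64 tumor. Leiden resolution 0.5 gave 0.071 for lipid genes. Resolution 2.0 gave dendritic cell shares of 0.521 tumor-free and 1.60 tumor, and in the tumor pair fibroblast G2 and M phase 0.10, lipid genes 0.10 and dendritic cell glycolysis -0.090. No doublet removal gave in the tumor pair a dendritic cell share of 1.75, lipid genes 0.11 and pericyte hypoxia 0.0068.

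Leaving out cluster 5 takes cells almost only from the tumor-free demineralized library, so the fibroblast share ratios it gave, 1.32 for mineralized over demineralized, tumor-free, and 1.29 for tumor over tumor-free, demineralized, follow from that choice and test nothing. Without it tumor-free fibroblast medians were 0.089 for hypoxia, -0.0099 for contractile, 0.30 for inflammatory and -0.13 for osteogenic genes. Without clusters 1, 15 and 23, the macrophage share ratio was 2.39 for mineralized over demineralized, tumor-free, and 2.27 for tumor over tumor-free, demineralized. Cluster 1 held 61.0% of the macrophages of the tumor-free demineralized library, so these ratios follow from that choice as well and test nothing. Fibroblast extracellular matrix was 0.040 and osteogenic genes -0.11 in the tumor pair. In tumor-free macrophages monocyte genes were at 0.17, Gpr65 at 0.0040 and Id2 at 0.15, and for tumor over tumor-free, demineralized, G2 and M phase was at -0.20 and cytokines at 0.47. The cytokine value also follows from the choice, since genes of that list are among those that lead cluster 1.

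Tumor cells thinned to 2000 UMIs gave S phase -0.11, G2 and M phase 0.088, stem cell genes 0.082 and KRT17 0.29. At most 10% mitochondrial UMIs gave stem cell genes 0.17, IFIT1 -1.55, HERC5 -0.66, IFIT3 -1.51 and TENT5A -0.14, -1.91 for IFIT2 in tumor cells, mineralized over demineralized, tumor libraries, in the tumor pair fibroblast G2 and M phase 0.093, lipid genes 0.12 and endothelial hypoxia -0.078, and tumor-free dendritic cell G2 and M phase -0.021. No filter on low counts gave stem cell genes 0.0036 and fibroblast osteogenic genes -0.0018 tumor-free and -0.019 tumor.

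Mouse cells thinned to 1000 UMIs gave, in fibroblasts, inflammatory genes 0.25 (tumor-free), S phase -0.062, extracellular matrix 0.014 and osteogenic genes -0.21 (tumor), and dissociation stress -0.016 (tumor over tumor-free, mineralized). In macrophages they gave MHC class II -0.0040 and monocyte genes 0.20 (tumor), and for tumor over tumor-free, mineralized, G2 and M phase -0.016 and cytokines -0.10. In pericytes they gave G2 and M phase -0.26, hypoxia 0.10 and Cfap43 0.23 (tumor-free), S phase 0.15, hypoxia -0.075 and glycolysis -0.21 (tumor), and S phase -0.13 (tumor over tumor-free, demineralized). Dendritic cell G2 and M phase was -0.37, endothelial glycolysis -0.37 and angiogenic genes -0.21 (tumor-free), and endothelial glycolysis -0.10 (tumor).

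A mean over cells of each cell's CPM gave, in the tumor pair, fibroblast S phase 0.091, G2 and M phase -0.019 and osteogenic genes -0.12, lipid genes 0.11, pericyte hypoxia -0.15, and endothelial G2 and M phase 0.32, hypoxia -0.24 and glycolysis -0.060. It gave endothelial G2 and M phase 0.22 tumor-free, and for tumor over tumor-free, mineralized, fibroblast stress -0.039 and macrophage G2 and M phase 0.00048. Tags at a probability of 0.99 or more were 25.4% tumor-free mineralized, 18.9% tumor-free demineralized and 31.6% tumor demineralized.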

Other observations

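The test of human RNA uptake in this part was chosen before its result was seen.

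Schwann cells, the glia of peripheral nerves, were 58 cells (1.77%) and 53 cells (1.71%) on the tumor mineralized and demineralized scaffolds against 26 cells (0.520%) and 4 cells (0.0867%) without tumor, 3.41-fold (2.11 to 5.65) and 19.8-fold (7.28 to 75.2). Natural killer and other lymphoid cells were 2.00% of mouse cells (62 cells) on the tumor demineralized scaffold, 1.93-fold the share without tumor (1.30 to 2.87), against 1.08%, 1.04% and 0.856% in the other libraries. B and plasma cells were 0.460, 0.238, 0.459 and 0.582% in the tumor-free mineralized, tumor-free demineralized, tumor mineralized and tumor demineralized libraries, in a cluster that also holds the plasmacytoid dendritic cell marker Siglech. Their ratio of tumor over tumor-free on demineralized scaffolds was 2.44 (1.09 to 5.72), and 0.872 when cells needed at least 500 genes.

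Human UMIs reached every mouse class large enough to read in the tumor libraries. Fibroblasts had means of 14.9 and 26.8 human UMIs per cell on mineralized and demineralized scaffolds and macrophages 7.62 and 21.4. As a hypothesis, macrophages that took up tumor cell material would hold more of it than fibroblasts. Above the tumor-free level, macrophages had 0.840 times the human UMIs of fibroblasts on mineralized and 0.948 times on demineralized scaffolds, which is not the excess predicted. Fibroblasts hold more UMIs per cell, however, and as a share of UMIs human RNA was higher in macrophages, 0.114% against 0.0838% and 0.271% against 0.179%. It was higher still in neutrophils, 0.282% and 0.932%, and in natural killer and other lymphoid cells, 0.132% and 0.286%, so a higher share is not particular to macrophages. Macrophages also had more human UMIs above the tumor-free level than endothelial cells, 5.07 against 3.50 and 18.4 against 12.5 per cell, so uptake is neither shown nor excluded. Of 960 macrophages in the tumor demineralized library, 4 had 200 or more human UMIs, as had 1 of 1425 fibroblasts.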
